A study of Mus musculus with 12 samples.

How the data were processed

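RNA-seq libraries were prepared from GFP-positive leukaemia cells sorted from the bone marrow of 12 mice, 1 library per mouse. The leukaemia was driven by MLL-AF9, a fusion oncoprotein of human acute myeloid leukaemia. The vehicle group held 5 mice. Of the mice given doxorubicin, a topoisomerase poison, with cytarabine, a nucleoside analogue, 3 were sampled 3 days after treatment ended (iCT) and 4 were sampled 10 days after it (relapse). Groups were taken from the sample titles, which number the mice within each group. RNA was extracted with a Qiagen RNeasy micro kit and libraries were made with NEB kits, per the labels' protocols. Read length, strandedness and the sorting gate beyond GFP are not given in the sources used here.

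Each deposited table was a Cufflinks gene table of 24883 entries in FPKM (fragments scaled to transcript length and to the mapped fragments of the library) with the bounds of a 95% confidence interval, per the file headers. The authors made these FPKM values with STAR and Cufflinks, per the submitters' processing notes, which give no version or option. The gene model set, the treatment of reads that map to several places and any scaling between libraries are not given in the sources used here. The notes name mm9, but of 23072 symbols with a single locus that were also found in GENCODE M21, 22934 (99.4%) overlapped the GRCm38 gene of the same name, and 12949 shared its start or end to the base. Coordinates are therefore given as the files hold them, with GRCm38 as the build. The tables held 24346 different symbols, and 817 entries belonged to symbols with several loci, which were kept apart by locus. Entries with a failed estimate in any library (2 genes) were left out. The tables held 0 entries on the mitochondrial chromosome, so the share of mitochondrial RNA was not analysed here. No pair of libraries had identical values (0 pairs).

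FPKM divides each gene's fragments by its length and by the library's total. A change in a few abundant genes therefore moves every other gene, and reads shared by near-identical genes depend on how Cufflinks divided them. The number of fragments behind a value is not in the tables. It was estimated as the square of 2 times the FPKM over the half-width of its interval. Between 37.7% and 43.9% of genes with low values per library gave a whole number within 0.02, so whole reads were not recovered for most genes and no count-based test was run. The implied depth was 362268 to 8362627 fragments per library. The median gene at an FPKM of at least 1 rested on 13.9 implied fragments in the shallowest library (iCT mouse 1) and on 43.9 to 293 in the others. These depths cover counting error only.

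Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with an FPKM of at least 1 in at least 3 libraries were tested (11019 genes). One linear model held all 12 libraries with group as its only term, so the groups shared 1 estimate of the spread. Prior variance followed a trend on mean expression, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The 3 group comparisons and an F test over the groups came from the same fit.

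The comparisons, named-gene rule, gene lists and most alternatives were fixed before the data were examined. The 45 lists held 1229 entries on metabolic pathways, cell cycle and repair, stress programmes, leukaemia and stem cell programmes, myeloid maturation and other marrow cell types. Of these, 1211 were found and 991 tested. Lists with at least 5 tested members (43 lists) were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 43 lists within a comparison. Camera with an estimated correlation and fry were run as alternatives. Named genes were the 8 with the largest rise and the 8 with the largest fall in iCT against vehicle, and 5 and 5 in the other comparisons. They had to pass the threshold, reach a group mean FPKM of 5 and have every library of one group above every library of the other. From each list up to 4 members (up to 3 for lists that did not pass) with the smallest p were taken, and 20 genes on nucleotide and glutamine metabolism, proliferation and leukaemia were always given where tested. Some genes that this rule names are not reported here. Spreads are SDs over mice.

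The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at an FPKM of 5, median-of-ratios scaling, quantile normalization, array weights (statmod 1.5.0), no variance trend, a fit of only the groups compared, a block on mouse number, and the omission of each library in turn. Precision weights from the intervals and the removal of trends on transcript length and GC content were added after the data were seen. Genes with a length and GC value made up 96.2% of those tested. The fitting procedure was tested on simulated data made from the real means with a biological coefficient of variation of 0.3. It recovered 15% of 2-fold and 76% of 4-fold changes in iCT against vehicle, 24% and 95% in relapse against vehicle, and 11% and 75% in relapse against iCT, with 4, 1 and 3 false calls among 10872, 10892 and 10911 genes. The simulated spread was the same in every group and was not fitted to the real libraries. Their median SD of log2 values was 0.202 in vehicle, 0.37 in iCT and 0.164 in relapse. These rates therefore describe the simulated setting and not the recovery in the real data. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.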

Results

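Gene expression was measured by RNA-seq in MLL-AF9 leukaemia cells, sorted by their GFP from mouse bone marrow, to follow these cells through induction chemotherapy. The cells came from vehicle-treated mice (n = 5), from mice 3 days after doxorubicin and cytarabine (iCT, n = 3) and from mice 10 days after them (relapse, n = 4). Each library came from a separate mouse. Values are the deposited FPKM of Cufflinks, and fold changes are on the log2(FPKM + 1) scale.

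Depth differed widely between libraries. The intervals in the files implied 5759747, 2351134, 1226471, 5189377 and 6173864 fragments for vehicle mice 1 to 5, and 2782481, 7484475, 4915453 and 3681949 for relapse mice 1 to 4. The iCT libraries rested on 362268, 8362627 and 6229636 fragments. The shallow library, iCT mouse 1, had 10443 genes above 0, against 12403 to 14510 in the others. Its Spearman correlation with the others was 0.853 to 0.889, and it lay alone on the first principal component at 100.6, with the remaining libraries between -19.2 and 15. The second component held 11.9% of the variance and placed the vehicle mice at 5.2 to 29 and the relapse mice at -16.7 to -5.8. The median SD of log2 values within a group was 0.202 in vehicle, 0.37 in iCT (0.199 without mouse 1) and 0.164 in relapse.

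**Figure D1:**
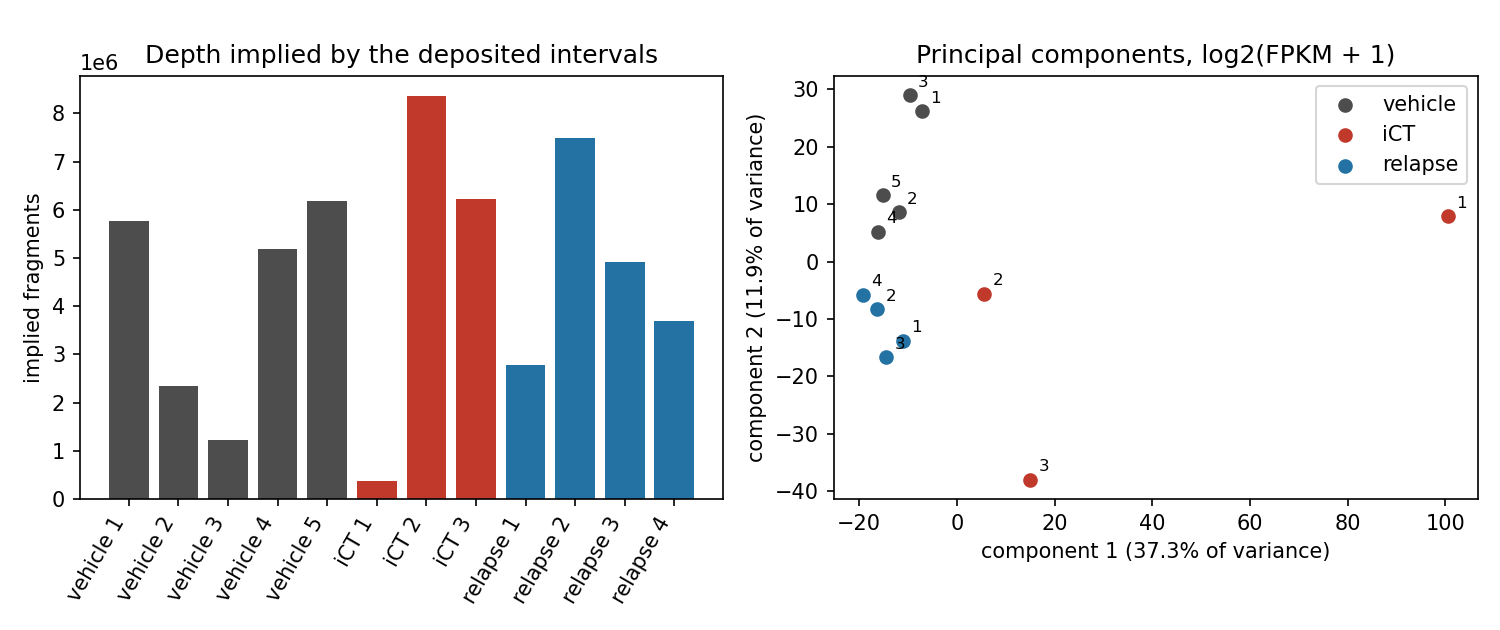
Left, implied fragments of each library, with bars coloured by group; iCT mouse 1 stands lowest at 362268. Right, libraries on the first (37.3% of variance) and second (11.9%) principal components of log2(FPKM + 1), where iCT mouse 1 lies apart at 100.6 and vehicle and relapse mice separate along the second component.

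The comparison of iCT with vehicle asked how surviving leukaemia cells differed 3 days after chemotherapy. The p53 targets Cdkn1a and Phlda3 rose, and the progenitor markers Kit and Cd34 and the niche receptor Cxcr4 fell. Of the genes of mature neutrophils 11 of 28 rose, and of tissue macrophages 11 of 19. Of the monocyte genes 4 of 26 rose and 11 fell, and of cholesterol synthesis genes 12 of 22 fell. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose from 15.4 ± 3.40 FPKM (SD, n = 5) to 89.9 ± 16.7 (n = 3). Kit, the stem cell factor receptor, fell from 25.8 ± 1.21 to 6.84 ± 1.65 FPKM. By limma, 1060 of 11019 genes differed, 365 higher and 695 lower in iCT, of which 117 and 241 changed at least 2-fold. A further view of separation was that in 1775 genes (16.1%) every iCT mouse lay on one side of every vehicle mouse, where chance gives 3.57%. The balance of directions depended on scaling, with 510 higher and 627 lower after median-of-ratios scaling, 526 and 570 after quantile normalization, and 693 and 665 after length and GC trends were removed. The count was 686 without iCT mouse 1, with 540 genes shared, 2722 without iCT mouse 2, 618 without vehicle mouse 3, 569 without vehicle mouse 5, 457 with array weights and 351 in a fit of these groups alone.

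The largest rises included genes of osteoclasts, a p53 target, stefins, a chemokine, a metallothionein and a complement gene of the macrophage list. Ctsk, the collagen-degrading cathepsin K of osteoclasts (chromosome 3, 95499210 to 95509387, GRCm38), rose from 0.91 ± 1.18 to 138 ± 121 FPKM, a log2 change of 6.06 (SE 0.96, adjusted p = 0.00341). Ctsk stood at 277 FPKM in iCT mouse 1 and at 75 and 61.1 in the others, and its change was 5.39 without that mouse. Phlda3, a p53-induced inhibitor of AKT (chromosome 1, 135766085 to 135769134), had a log2 change of 4.58 (SE 0.33, adjusted p = 3.42e-05). Acp5, the tartrate-resistant acid phosphatase of osteoclasts, rose by 3.18, or 2.47 without iCT mouse 1. The chemokine gene Ccl8 rose by 4.56 and the complement gene C1qc by 3.00. Stfa2 and Stfa2l1, protease inhibitors of the stefin A family, rose by 3.90 and 3.18, and both are uncertain because the family has near-identical copies. The metallothionein gene Mt3 rose by 3.46 (adjusted p = 0.0401), but stood at 150 FPKM in iCT mouse 1 and at 3.72 and 1.90 in the others. Its change was 1.67 without that mouse and 4.17 and 4.52 without iCT mice 2 and 3, and its adjusted p was 0.0534 to 0.078 whenever any vehicle or relapse mouse was left out.

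The largest falls led with Hbb-b1, a beta-globin with a near-identical copy (log2 change -4.27, SE 0.77, adjusted p = 0.00664; -4.94 without vehicle mouse 1), and Ly86, which encodes the MD-1 partner of a Toll-like receptor homologue (log2 change -4.07, SE 0.56, adjusted p = 0.00151). Ly86 (chromosome 13, 37345345 to 37419036) went from 59.1 ± 8.02 to 3.80 ± 3.31 FPKM, and its change was -3.16 without iCT mouse 1. Penk, which encodes proenkephalin, changed by -2.39, the integrin gene Itgb7 by -2.38 and the carboxypeptidase gene Scpep1 by -2.38. Acyp1, an acylphosphatase gene, changed by -2.95, or -1.41, -3.90 and -3.55 without iCT mice 1, 2 and 3, and its adjusted p of 0.0384 became 0.0527 to 0.0784 whenever any vehicle or relapse mouse was left out. Smim24, a small membrane protein gene, changed by -2.93, or -1.63 and -3.75 without iCT mice 1 and 2. H2-T22, a non-classical MHC class I gene with close paralogs, changed by -2.41 (-3.01 without iCT mouse 2) and lost its call without iCT mouse 1 (-1.69, adjusted p = 0.0729) and without vehicle mouse 3 (0.0529).

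Among 30 tested p53 targets, 10 rose and 1 fell, or 12 and 2 when adjusted over the list alone. Besides Phlda3 and Cdkn1a, Zmat3, an RNA-binding growth suppressor, rose by 2.22 (SE 0.19, adjusted p = 8.67e-05) and cyclin G1 (Ccng1) by 1.02 (adjusted p = 0.00471). Mdm2, which encodes the ligase that degrades p53, had a log2 change of 0.46 (adjusted p = 0.149). The list passed camera (adjusted p = 9.71e-07), with adjusted p = 0.0972 with an estimated correlation. Proliferation genes moved little as groups. In the list of G2 and mitosis, 0 of 43 members rose and 3 fell, in the list of DNA replication 1 of 38 rose and 1 fell, and neither list passed camera (adjusted p = 0.941 and 0.887); the counts adjusted over the list alone were the same. Their medians (-0.08 and -0.05) lay below 0 while camera ranked both above other genes. The mitotic phosphatase gene Cdc25b fell (log2 change -1.38, adjusted p = 0.00488), as did Nusap1, a spindle protein gene, by 0.61. Top2a, the topoisomerase that doxorubicin poisons, fell by 0.57 (adjusted p = 0.0214, or 0.052 without vehicle mouse 5), whereas Mki67, a proliferation marker, had a log2 change of 0.49 (adjusted p = 0.177).

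Of 7 tested haematopoietic stem cell genes (of 21 entries) 0 rose and 2 fell (4 fell when adjusted over the list alone), and the list passed camera (adjusted p = 0.00499; 0.0972 with an estimated correlation; 0.0681 without iCT mouse 2). With no filter on expression its adjusted p was 0.748 and its median went from -0.64 to -0.04. Cd34, a marker of stem and progenitor cells (chromosome 1, 194938821 to 194961292), changed by -1.69 (SE 0.16, adjusted p = 0.00017), from 89.7 ± 18.8 to 26.9 ± 4.09 FPKM, and Adgrl4, an endothelial and stem cell receptor gene, by -0.85. The leukaemia stem cell programme of MLL-AF9 as a list did not pass (adjusted p = 0.799), with 0 of 23 members higher and Kit and Cd34 (2 genes) lower, or 2 higher and 4 lower adjusted over the list alone. Its central factors Hoxa9 and Meis1 had log2 changes of 0.26 (SE 0.14) and -0.30 (SE 0.22). Cxcr4, the receptor that holds cells in the marrow niche, changed by -1.03 (SE 0.12, adjusted p = 0.000613), and Cd38, an ectoenzyme of the same adhesion and niche list, by 2.26. That list had 1 of 21 members higher and 5 lower (2 and 7 adjusted over the list alone) and did not pass (adjusted p = 0.137).

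**Figure D2:**
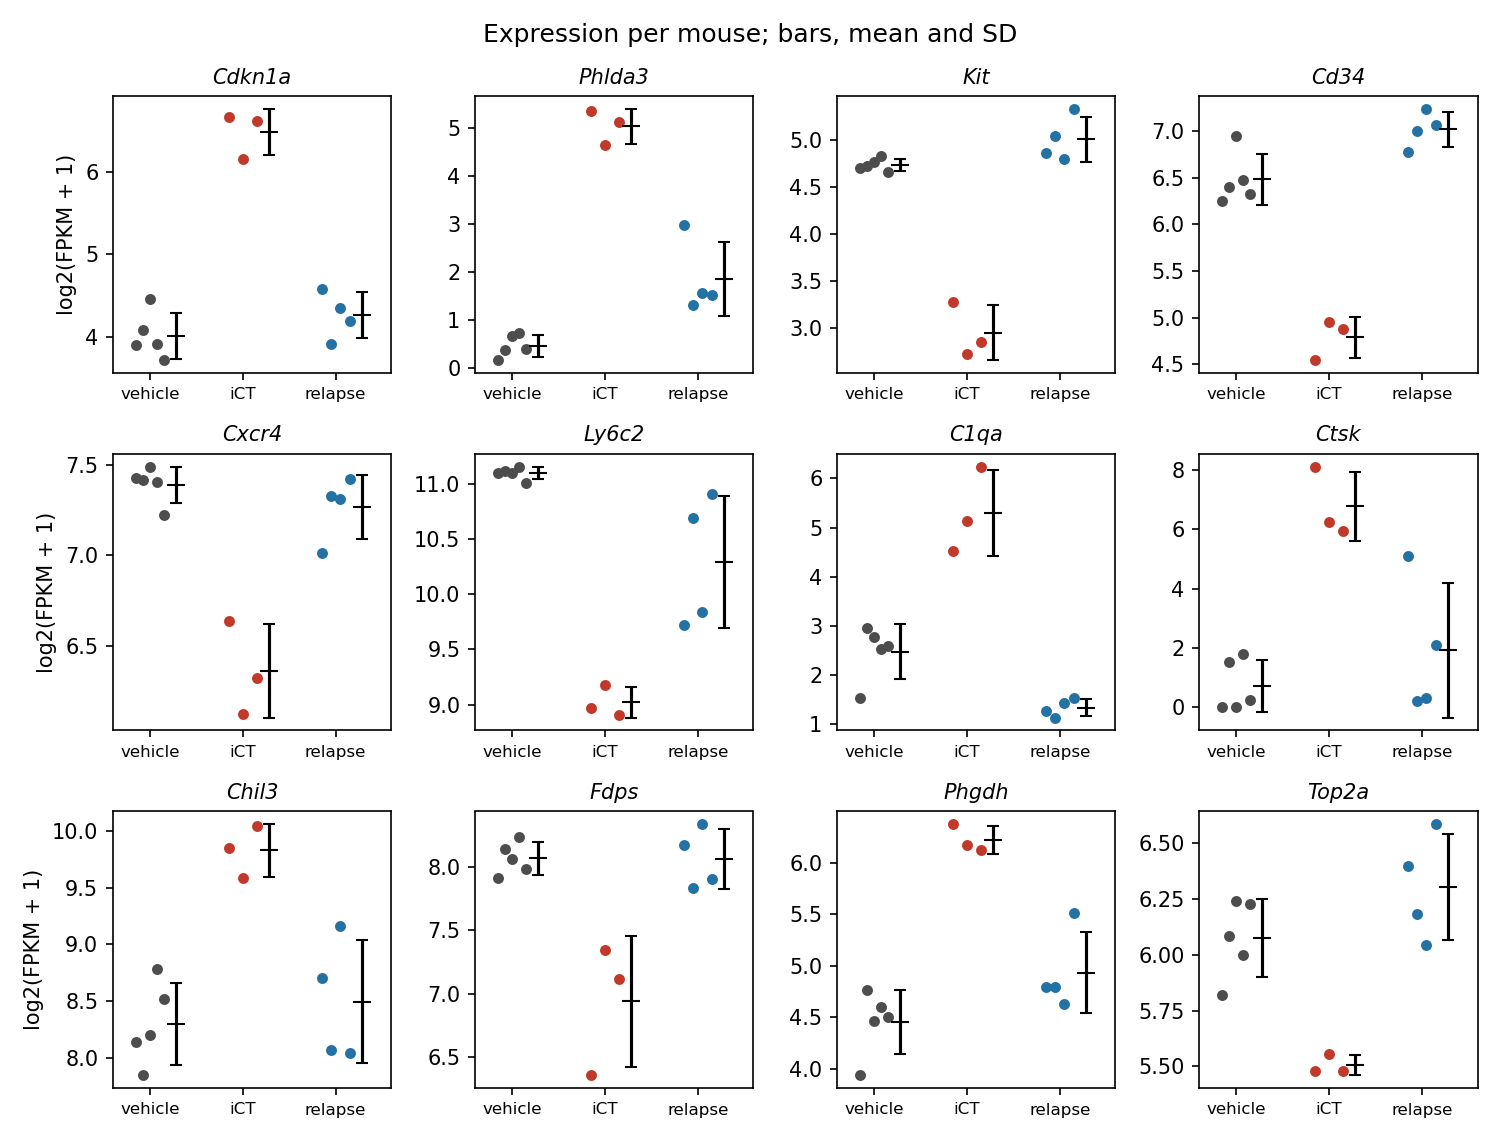
Expression of 12 genes as log2(FPKM + 1); each point is a mouse (vehicle 5, iCT 3, relapse 4) and bars give the mean and SD. Cdkn1a and Phlda3 are high and Kit, Cd34 and Cxcr4 low in every iCT mouse. C1qa varies among the iCT mice. Ctsk spans 61.1 to 277 FPKM in the iCT mice and 0.152 to 33.1 FPKM in the relapse mice.

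Myeloid genes changed in both directions. Of 28 genes of secondary granules and mature neutrophils 11 rose and 0 fell, or 17 and 2 adjusted over the list alone. Chil3, a chitinase-like lectin, rose by 1.53 (SE 0.26, adjusted p = 0.00478), the gelatinase gene Mmp9, which osteoclasts also express, by 2.69 and the annexin gene Anxa1 by 0.66. The list passed camera (adjusted p = 1.95e-07), with adjusted p = 0.402 with an estimated correlation and 0.0536 with fry. Of 26 monocyte genes 4 rose and 11 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.0709). The monocyte antigen Ly6c2, which has a close paralog in Ly6c1, changed by -2.08 (SE 0.23) and Ly6c1 by -1.97. Irf8, a transcription factor of monocyte and dendritic cell development, changed by -2.04 (SE 0.29, adjusted p = 0.00158). Ms4a3, a gene of granulocyte-monocyte progenitors, rose by 2.06 (SE 0.21, adjusted p = 0.000192), although its list of progenitor and primary granule genes went both ways, with 3 of 20 higher and 2 lower (camera adjusted p = 0.387).

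Of 28 entries of the tissue macrophage list 19 were tested, of which 11 rose and 1 fell, or 13 and 1 adjusted over the list alone. The complement genes C1qa, C1qb and C1qc changed by 2.82, 2.71 and 3.00, and C1qa went from 4.87 ± 1.83 to 43.6 ± 27.6 FPKM. Mrc1, the mannose receptor, rose by 1.94 (adjusted p = 0.000974), but lay under 1 FPKM in every vehicle and relapse mouse. It passed the filter on expression only through the 3 iCT mice and was not tested without iCT mouse 1. The 1 lower member, Adgre1, chosen after its values were seen, encodes F4/80 and fell by 1.87 (adjusted p = 0.000192). The list passed camera (median log2 change 1.36, adjusted p = 1.95e-07), with adjusted p = 0.0972 with an estimated correlation. Markers of other marrow cells went several ways. Of 5 plasma cell genes 1 rose, Trp53inp1, itself a p53 target (log2 change 0.85, adjusted p = 0.019); the list passed (adjusted p = 0.0209; 0.141 with an estimated correlation; 0.154 without iCT mouse 2; 0.11 with a filter at an FPKM of 5), with 3 members higher adjusted over the list alone. Of 12 erythroid genes 0 rose and 3 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.0826), and of 6 T and natural killer cell genes none passed (0 past the limma threshold, 0 adjusted over the list alone). Pf4, which encodes platelet factor 4, rose by 2.75 (adjusted p = 0.00342) in a megakaryocyte list in which the other 4 members did not pass. Among 11 stromal and endothelial genes 2 rose and 1 fell (camera adjusted p = 0.364). Lpl, shared with the macrophage list, and Igfbp4 rose by 1.45 and 0.95, and the endothelial gene Pecam1 changed by -0.82.

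Of 22 tested cholesterol synthesis genes 0 rose and 12 fell, or 15 adjusted over the list alone, and all had a negative change (camera adjusted p = 4.06e-07; 0.307 with an estimated correlation). Fdps, farnesyl diphosphate synthase (chromosome 3, 89093588 to 89101967), went from 269 ± 24.2 to 127 ± 41.7 FPKM, a log2 change of -1.13 (SE 0.19, adjusted p = 0.00474). Squalene epoxidase (Sqle) changed by -1.02, the sterol desaturase gene Sc5d by -0.91 and the sterol sensor gene Insig1 by -0.93. Of 22 targets of hypoxia-inducible factor 0 rose and 6 fell (1 and 8 adjusted over the list alone). The collagen hydroxylase gene P4ha1 changed by -0.99 and the oxygen sensor genes Egln3 and Egln1 by -0.82 and -0.48. That list passed (adjusted p = 0.023), with adjusted p = 0.264 with an estimated correlation and 0.186 without iCT mouse 2.

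Some genes of amino acid stress and ribosome biogenesis rose. Of 27 ATF4 targets 7 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 4.27e-06; 0.0972 with an estimated correlation). The aminoacyl-tRNA synthetase genes Wars, Tars and Aars rose by 0.57, 0.58 and 0.53. Sesn2, a sensor of leucine, rose by 1.21. Without iCT mouse 1 the adjusted p was 0.0578 for Aars and 0.0532 for Sesn2, and without iCT mouse 3 it was 0.0511 for Sesn2. Of 38 MYC targets and ribosome biogenesis genes 8 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 4.06e-07; 0.264 with an estimated correlation). They included Srm, spermidine synthase (log2 change 0.56), and Nolc1, a nucleolar factor (0.79). In the list of serine synthesis and one-carbon metabolism 2 of 16 rose and 0 fell (4 adjusted over the list alone). Phgdh, the first enzyme of serine synthesis, rose from 21.3 ± 4.40 to 73.9 ± 7.20 FPKM (log2 change 1.77, SE 0.21, adjusted p = 0.000553). The list's adjusted p of 0.0261 was 0.159 with an estimated correlation, 0.0541 after quantile normalization, 0.0502 without vehicle mouse 5 and 0.139 without iCT mouse 2.

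De novo pyrimidine synthesis did not move as a list (median 0.00, mean 0.02; 1 of 17 higher, 1 lower; 3 and 1 adjusted over the list alone; camera adjusted p = 0.432). Rrm2, a subunit of ribonucleotide reductase, rose by 0.51 (SE 0.10, adjusted p = 0.0127), and the kinase gene Cmpk1 changed by -0.59 (adjusted p = 0.0248). Log2 changes of the pathway's enzymes Cad, Dhodh and Umps were 0.53 (SE 0.21, adjusted p = 0.117), 0.12 (SE 0.13) and 0.00 (SE 0.14), and Cad stood at 14.9 FPKM in vehicle mouse 1 against 25.1 to 30 in the other vehicle mice. Glutamine and aspartate genes did not pass as a list either (2 of 22 higher, 0 lower; 3 and 0 adjusted over the list alone; camera adjusted p = 0.341). The amino acid exchanger genes Slc7a5 and Slc3a2 rose by 0.52 and 0.53. Glutamine synthetase (Glul), the glutamine carrier Slc1a5 and the transaminases Got1 and Got2 had log2 changes of 0.21, 0.04, 0.01 and 0.39, with adjusted p from 0.0556 for Got2 to 0.956. Nuclear genes of the respiratory chain stayed close to vehicle, with 1 of 72 higher and 2 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.707). The remaining fixed genes Myc and Bcl2 had log2 changes of 0.39 (adjusted p = 0.163) and 0.40 (adjusted p = 0.403).

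**Figure D3:**
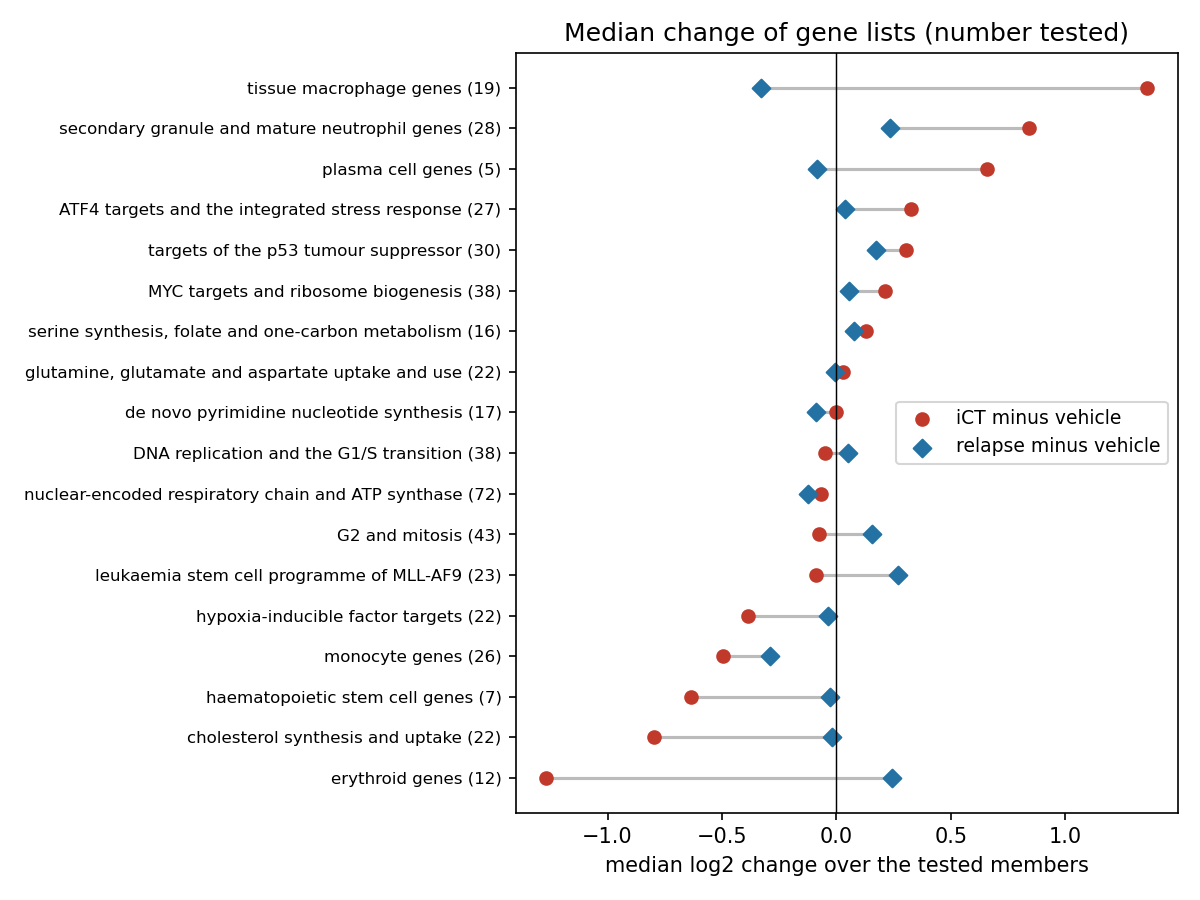
Median log2 change over the tested members of 18 gene lists, iCT minus vehicle (circles) and relapse minus vehicle (diamonds), with the number of tested members in brackets and a line joining the values of a list. Tissue macrophage genes lie at 1.36 in iCT and -0.33 in relapse, and cholesterol synthesis at -0.80 and -0.02.

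The comparison of relapse with vehicle asked whether leukaemia cells 10 days after chemotherapy differed from untreated ones. No gene passed the threshold (0 of 11019 by limma, lowest adjusted p = 0.173), although 1604 genes (14.6%) had an unadjusted p under 0.05 and the groups were separated in 1515 (13.7%, chance 1.59%). Kit stood at 31.6 ± 5.64 FPKM (SD, n = 4), Cd34 at 129 ± 16.9 and Cdkn1a at 18.4 ± 3.72, with log2 changes against vehicle of 0.27, 0.54 and 0.25. Flt3, a receptor tyrosine kinase of progenitors, had the value of 8.93 ± 3.46 FPKM against 1.81 ± 0.584 (log2 change 1.78, SE 0.32, adjusted p = 0.173), and lay higher in all 4 relapse mice than in any vehicle mouse. Phlda3 had a change of 1.39 (SE 0.31), with 6.93 FPKM in relapse mouse 1 and 1.49 to 1.96 in the others.

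The 0 depended on the estimate of spread, which the iCT libraries share. In a fit of relapse and vehicle alone 612 genes passed (409 higher, 203 lower), with array weights 971 (646 and 325, of which 553 were shared), with precision weights 7 and without iCT mouse 1 5. In the fit of these groups alone the rule for named genes gave Flt3 (adjusted p = 0.0196), the cell junction gene Cgnl1, the dynein gene Dync1h1, the calcium channel gene Itpr3 and the gluconeogenic gene Fbp1 as higher. It gave Rgs20, a regulator of G protein signalling, Tmem220, Hspb7, a small heat shock protein gene, Cxcl15 and the junctional adhesion gene F11r as lower. Across genes, which are not independent replicates, the change from vehicle to relapse had a Spearman correlation of 0.245 with transcript length and 0.353 with GC content. With both trends removed that fit called 24 genes, 22 of them among the 612.

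At the level of lists, 10 of 43 passed camera with the preset correlation and 0 with an estimated one, and 0 of their members passed alone. Fry ended 9 of the 10 calls and kept that on the MLL-AF9 programme (adjusted p = 0.046). The leukaemia stem cell programme of MLL-AF9 lay higher (median log2 change 0.27, adjusted p = 0.00221; 0.626 with an estimated correlation; median 0.12 and adjusted p = 0.00372 with length and GC trends removed), led by Flt3, and 2 members were higher when adjusted over the list alone. Genes of G2 and mitosis also lay higher (median 0.16, adjusted p = 0.00569; 0.641 with an estimated correlation; 0.0965 with array weights), with 2 higher adjusted over the list alone. Their values included 0.62 for the kinesin gene Kif20a, 0.52 for the condensin gene Ncapd2 and 0.71 (adjusted p = 0.182) for Mki67. Interferon-stimulated genes lay lower (median -0.26, adjusted p = 2.07e-07; 0.641 with an estimated correlation; 0 adjusted over the list alone), including Rtp4 (-0.97) and Rsad2 (-0.80). Macrophage genes (median -0.33, adjusted p = 1e-04; 0.626 with an estimated correlation) and monocyte genes (median -0.29, adjusted p = 8.22e-06; 0.641) lay lower too, with 2 and 3 members lower adjusted over the list alone, among values of -1.14 for C1qa and -0.81 for Ly6c2.

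Further lists lower in relapse were ribosomal proteins (median -0.13, adjusted p = 9.39e-12), the respiratory chain (-0.12, 1.74e-08) and primary granule genes (-0.11, 0.00248), each with adjusted p = 0.641 with an estimated correlation and 0 members past when adjusted over the list alone. After quantile normalization the adjusted p was 0.568 for ribosomal proteins and 0.262 for primary granule genes. Pyrimidine synthesis and endoplasmic reticulum chaperones were lower at an adjusted p of 0.044 each (0.641 with an estimated correlation; 0 members adjusted over the list alone). The call on pyrimidine synthesis was lost without vehicle mouse 3 or 4, iCT mouse 1, or relapse mouse 3 or 4 (adjusted p 0.0612 to 0.134), after quantile normalization (0.196), with a filter at an FPKM of 5 (0.142), with array or precision weights (0.0736 and 0.0688) and with length and GC trends removed (0.0621). That on chaperones was lost without vehicle mouse 3, 4 or 5, any iCT mouse, or relapse mouse 1 or 3 (0.0514 to 0.21), after quantile normalization (0.262), with a filter at an FPKM of 5 (0.101) and with precision weights (0.0712). Cad, Dhodh and Umps had log2 changes of 0.51 (adjusted p = 0.258), -0.04 and 0.03.

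The comparison of relapse with iCT asked what changed between 3 and 10 days, and it is also the test of whether the effects at these times differed. Kit, Cd34 and 10 of 22 cholesterol synthesis genes rose, and 8 of 30 p53 targets, 11 of 19 macrophage genes and 9 of 28 mature neutrophil genes fell. Cd34 had a log2 change of 2.22 (SE 0.17, adjusted p = 4.28e-05), Kit of 2.06 (SE 0.16, adjusted p = 4.28e-05) and Cdkn1a of -2.23 (SE 0.20, adjusted p = 0.000139). By limma 1071 of 11019 genes differed, 729 higher and 342 lower in relapse (251 and 199 at least 2-fold), and the groups were separated in 2564 genes (23.3%, chance 5.71%). The median change over all genes was 0.16 as deposited, 0.06 after median-of-ratios scaling and 0.02 after quantile normalization, and the split became 503 higher and 519 lower, and 431 and 420, respectively. With length and GC trends removed it was 499 and 714. The count was 1579 without iCT mouse 2, 1855 without iCT mouse 3, 593, 529, 583 and 536 without relapse mice 1 to 4, 603 with array weights, and 252 in a fit of these groups alone.

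The largest rises from iCT to relapse were in Hbb-b1 (3.89), Ly86 (3.71, SE 0.59, adjusted p = 0.00421; 2.79 without iCT mouse 1), Hbb-b2 (3.66), Retnlg (3.38), a resistin-like gene of neutrophils, and Cox7a1 (2.80), a respiratory chain subunit gene. Retnlg changed by 2.69 without iCT mouse 1 and 4.07 without iCT mouse 3, and Cox7a1 by 3.89 without iCT mouse 2. Without iCT mouse 1 the adjusted p was 0.068 for Hbb-b2 and 0.0838 for Cox7a1. Hbb-b2 also lost its call without relapse mouse 1, 2 or 4 (up to 0.0671), and Cox7a1 without iCT mouse 3 or relapse mouse 1, 3 or 4 (up to 0.0695). The largest falls were in Ctsk (-4.85, SE 1.01, adjusted p = 0.0133; -4.18 without iCT mouse 1 and -5.90 without relapse mouse 1), Ccl8 (-4.33), C1qa (-3.96, SE 0.38, adjusted p = 0.000201) and C1qc (-3.88). Eif3j1, an initiation factor subunit gene, had a change of -4.66 that is uncertain, because the transcript of its paralog Eif3j2 is near-identical.

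By list, p53 targets had 0 of 30 higher and 8 lower (1 and 13 adjusted over the list alone), including Phlda3 (-3.19), Zmat3 (-1.70) and Ccng1 (-1.22), with a camera adjusted p of 1.08e-06 and 0.0791 with an estimated correlation. Macrophage genes had 1 of 19 higher and 11 lower (1 and 14 adjusted over the list alone; median -1.75), the only one of 19 lists past the preset test that also passed with an estimated correlation (adjusted p = 9.08e-14 and 0.0484). Mature neutrophil genes had 1 of 28 higher and 9 lower (2 and 11 adjusted over the list alone; adjusted p = 1.62e-06; 0.345 with an estimated correlation), with Stfa2 at -3.84 and Chil3 at -1.33. Cholesterol synthesis had 10 of 22 higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 9.05e-06; 0.345 with an estimated correlation), led by Fdps (1.13), Sqle (0.89) and Dhcr7 (0.80). The adhesion and niche list had 7 of 21 higher and 2 lower (13 and 2 adjusted over the list alone; adjusted p = 0.0217; 0.345 with an estimated correlation; 0.0588 without iCT mouse 2), with Itgb7 at 2.22, the adhesion receptor gene Adgrg1 at 1.53 and Cxcr4 at 0.91.

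Stem cell genes had 3 of 7 higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.00506; 0.0791 with an estimated correlation; 0.0516 without iCT mouse 2; 0.596 with no filter on expression, where the median went from 0.63 to 0.05), including Gata2, a stem cell transcription factor (1.26). The MLL-AF9 programme had 5 of 23 higher and 0 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0262; 0.345 with an estimated correlation; 0.29 without iCT mouse 2). Primary granule genes had 2 of 20 higher and 4 lower (3 and 5 adjusted over the list alone; adjusted p = 0.00537; 0.345 with an estimated correlation; 0.0516 without iCT mouse 2; 0.155 after quantile normalization), led by Ms4a3 at -2.67. ATF4 targets had 0 of 27 higher and 4 lower (0 and 12 adjusted over the list alone; adjusted p = 1.87e-06; 0.0791 with an estimated correlation), and ribosome biogenesis genes had 0 of 38 higher and 5 lower (0 and 10 adjusted over the list alone; adjusted p = 1.62e-06; 0.291 with an estimated correlation). Rrm2 changed by -0.62 (adjusted p = 0.00663) and Top2a by 0.80 (adjusted p = 0.00589), whereas Cad, Dhodh and Umps had log2 changes of -0.03, -0.17 and 0.03. Car1, an erythroid carbonic anhydrase gene, changed by 2.03 (adjusted p = 0.0406). It was listed at 0 in all 3 iCT libraries, among them the shallow iCT mouse 1. Its call was lost in 9 omissions of a library (adjusted p 0.0524 to 0.1).

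Further lists also passed the preset test. Erythroid genes had 4 of 12 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.0256; 0.462 with an estimated correlation), and the list lost its call without iCT mouse 2 (0.113) or 3 (0.14) and with a filter at an FPKM of 5 (0.0624). Plasma cell genes had 0 of 5 higher or lower (3 lower adjusted over the list alone; adjusted p = 0.000759; 0.0759 with an estimated correlation). Endoplasmic reticulum chaperones had 0 of 20 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.00107; 0.345 with an estimated correlation). Purine and pyrimidine synthesis had 1 of 17 and 2 of 17 lower and 0 higher (1 and 4 lower adjusted over the list alone; adjusted p = 0.00506 and 0.023; 0.174 and 0.462 with an estimated correlation), and both lost their calls without iCT mouse 2 (0.107 and 0.406), and pyrimidine synthesis also after quantile normalization (0.0676). Serine and one-carbon genes had 2 of 16 lower, with Phgdh at -1.29 (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.0281; 0.197 with an estimated correlation). That call was lost without iCT mouse 2 (0.105) or 3 (0.0503) or relapse mouse 1 (0.0615), after quantile normalization (0.102) and with no filter (0.0802).

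The last lists past the preset test had medians near 0. The respiratory chain was ranked lower (adjusted p = 0.00309; 0.639 with an estimated correlation) with 0 of 72 higher and 1 lower, the same adjusted over the list alone. Its median was -0.06 and its mean 0.01, and without iCT mouse 2 the adjusted p was 0.958 and the median 0.06. After quantile normalization its adjusted p was 0.488. Ribosomal proteins had 0 of 76 higher or lower, also adjusted over the list alone, and were ranked lower (median -0.03, adjusted p = 0.0033; 0.71 with an estimated correlation). Without iCT mouse 2 their median was 0.12 (adjusted p = 0.694), and after quantile normalization it was 0.03 (0.601). Apoptosis regulators of the BCL2 family were ranked lower at a median of 0.03 and a mean of -0.13, with 0 of 17 higher and 2 lower (3 lower adjusted over the list alone; adjusted p = 0.0303; 0.345 with an estimated correlation). That call was lost without iCT mouse 2 (0.107) or 3 (0.159), with a pseudocount of 0.1 (0.0542), no filter (0.0716), median-of-ratios scaling (0.0587), the length (0.0771), GC (0.0575) or both trends removed (0.0707), and fry (0.626).

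The F test over the groups passed 1033 genes. The changes of iCT and relapse from vehicle had a correlation of 0.25 across genes, below the mean of 0.415 for simulated unchanged groups that share the vehicle libraries. A change in 1 group alone also lowers this correlation, so the lower value does not speak against shared change. The covariance of these changes was 0.0505 against 0.0358 simulated. The simulation gave every library the same spread for a gene. The real median SD was 0.202 in vehicle, 0.37 in iCT and 0.164 in relapse. Neither simulated value is therefore a baseline that can decide whether the changes are shared. With the vehicle mice divided between the comparisons the correlation was -0.01 to 0.165 and the covariance -0.0026 to 0.0353 over 20 divisions. Of the 365 genes higher in iCT, 163 (44.7%) fell again significantly from iCT to relapse. Over all 365 the median change from vehicle went from 0.73 in iCT to 0.19 in relapse. Of the 695 lower genes 408 (58.7%) rose again, and over all 695 the median went from -0.84 to -0.10. The 571 genes that turned back compare with 57.3 for independent lists, but both comparisons use the same iCT libraries, which alone raises the overlap. The genes were selected by their change in iCT from vehicle, which alone enlarges the iCT medians. This selection also pushes the relapse medians in the same direction, because the same vehicle mice are used. In relapse 286 (78.4%) of the higher and 465 (66.9%) of the lower genes kept the sign of the iCT change. With the vehicle mice divided, the relapse medians were 0.106 to 0.265 and -0.132 to -0.069. The genes were still selected with all vehicle mice there.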

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

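The tests of cell source, of length, GC content and scaling, and of shared reads below were chosen after the patterns were seen, whereas the counts over other splits of the libraries were planned.

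The effects of iCT and relapse against vehicle differed by the direct test between them for 1071 of 11019 genes. Of the 105 tested genes named in the text 75 were among these, but many of the 105 were chosen by their results in these comparisons. Other splits of the 7 libraries gave at most 3 genes. The real split gave the highest count (1 of 35 splits as large, 2.9%). That is the smallest share that 35 splits can give, so chance is unlikely but not excluded. Splits that mix the groups add the group difference to the spread, which lowers their counts and limits what the gap shows. By camera with the preset correlation, 19 lists differed, and other splits gave at most 18. The real split gave the highest count (1 of 35 as large), but a margin of 1 list is too small to exclude chance. Leaving out iCT mouse 2 ended 11 of the 19 calls and fry ended 10, and 1 list passed with an estimated correlation. Ranked below other genes in relapse, whose median change was 0.16, were genes of macrophages (adjusted p = 9.08e-14), mature neutrophils (1.62e-06), primary granules (0.00537) and plasma cells (0.000759). So were targets of p53 (1.08e-06) and ATF4 (1.87e-06), ribosome biogenesis (1.62e-06), ribosomal proteins (0.0033), the respiratory chain (0.00309), chaperones (0.00107), the BCL2 family (0.0303) and synthesis of purines (0.00506), pyrimidines (0.023) and serine (0.0281). The direction of 2 of these lists depended on the measure. The respiratory chain had a median of -0.06 and a mean of 0.01, and the BCL2 family a median of 0.03 and a mean of -0.13. Ranked above other genes were cholesterol synthesis (9.05e-06), stem cell genes (0.00506), the MLL-AF9 programme (0.0262), erythroid genes (0.0256) and adhesion genes (0.0217).

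Chance is likewise unlikely but not excluded for the 1060 genes of iCT against vehicle (highest other split 147, 1 of 56 as large). The same holds for the 1033 genes of the F test (highest other 3, 1 of 100). Counts as large came up more often for the 10 lists of iCT against vehicle (highest other 13, 8 of 56 as large). They also did for the 10 lists of relapse against vehicle (highest other 15, 24 of 100), so chance stays open for both. For single genes in relapse against vehicle the real count was 0 and the highest other 3 (100 of 100 as large). The 612 genes of the fit of these groups alone exceeded every other split (highest 5, 1 of 100), so chance is unlikely there.

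In the vehicle and relapse groups a single mouse stood far from the rest in 15 of 214 tested groups of values, where chance gives about 1 in 20, or 10.7. The 3 iCT mice were not tested in this way, so their absence below is not a result. Vehicle mouse 1 was lowest for Cad (14.9 FPKM; others 25.1 to 30), Got1 (19.3; 23.2 to 24.8), Aars (38.1; 44.8 to 47.5), Gbp3 (15.6; 28.2 to 34.1) and Retnlg (16.6; 123 to 190), and highest for Cxcl15 (32.5; 10.2 to 14.3). Vehicle mouse 3 was highest for Ccng1 (59.4; 37.1 to 41.4) and lowest for Gata2 (3.12; 5.68 to 6.51). Vehicle mouse 2 (1.11 FPKM) and relapse mouse 1 (0.933) had Mt3 where the others of their groups were listed at 0. Relapse mouse 1 was highest for Phlda3 (6.93; 1.49 to 1.96). Relapse mouse 4 was highest for Scpep1 (36.1; 22.6 to 23.7) and Ccnd2 (1.58; 0.961 to 1.01) and lowest for Dhodh (14.6; 16.7 to 17). Vehicle mouse 4 was lowest for Eif3j1 (0.337; 33.2 to 77.5).

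Of 19 macrophage genes 11 rose in iCT (camera adjusted p = 0.0972 with an estimated correlation). A general loss of leukaemia cells from the sorted fraction would raise every other cell type, if these kept their proportions to each other. The other lists went both ways. T and natural killer cell genes (6 tested) had an upper quartile of -0.192 and erythroid genes of -0.099. Plasma cell, stromal, megakaryocyte and mast cell genes had upper quartiles of 0.853, 0.755, 0.376 and 0.271. Whether the proportions were kept after chemotherapy is not known, so this explanation stays open. Macrophages or their RNA in the fraction, which the GFP sort would be meant to remove, and a macrophage-like state of the leukaemia cells cannot be told apart, since either would raise these genes and the list had already been seen to rise. With a vehicle mean above 0 and under 5 FPKM, 18 of 19 macrophage genes had a higher mean in iCT (94.7%; 38.2% of all other genes in that range), with C1qa at 43.6 FPKM and 3 of the 28 entries also in other lists, while the 7 above 5 FPKM went both ways (median 0.044, quartiles -0.262 and 0.918). Osteoclasts or their RNA stay open in the same way: 5 of 6 such low osteoclast genes not seen before were higher (83.3%), with Ctsk at 138 FPKM, and the 8 above 5 FPKM went both ways (5 with a positive change, median 0.225).

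Relapse and vehicle differed by 612 genes in the fit of these groups alone. Bias by transcript length and GC content may underlie most of these calls, since 24 passed with both trends removed; the calls ended because the folds shrank (median size 0.56 before, quartiles 0.45 and 0.71, and 0.34 after, quartiles 0.24 and 0.49), while the median SE went from 0.12 to 0.10 and 611 of 612 kept their sign. The trends are argued against as the whole source of the preset call on ribosomal proteins, which stayed with both removed (adjusted p = 1.36e-06), although that call is lost with an estimated correlation (0.641) and with fry (0.556). Scaling of the libraries stays open for that list, as the methods differed: quantile normalization ended the call (adjusted p = 0.568; median -0.134 before and -0.005 after), whereas median-of-ratios scaling kept it (adjusted p = 3.83e-14; median -0.199). A biological change in relapse also stays open, for all these genes, and was not tested.

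In 7 of 12 libraries Eif3j1 or Eif3j2 lay below 1 FPKM and the other at 46.4 to 77.5, and in 5 both lay at 19.8 to 39.2. Division of shared reads between these paralogs is a candidate explanation: 95.1% of the 25-base words of the shorter transcript occur in the other. The SD of log2 values was 2.55 and 1.93 for the genes and 0.24 for their sum, which ranged from 46.7 to 78.4 FPKM. No biological explanation was tested.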

How the results depend on the processing

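Precision weights, the removal of length and GC trends, and its combination with a fit of the groups compared alone were chosen after the data were seen; the other alternatives were planned.

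Over 104 alternative counts, 70 stayed within 1.5 times the reported count. Over 975 alternative tests of lists past the preset test, 856 kept direction and side of the threshold, 116 lost the call and 3 reversed the direction of the test. Over 5261 for named genes, 4877 kept both, 240 lost a call, 144 gained one and 0 reversed.

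For iCT against vehicle, 1060 genes became 457 with array weights and 351 in a fit of these groups alone, and 569 (without vehicle mouse 5) to 2722 (without iCT mouse 2) when 1 library was left out. The count also fell to 618 without vehicle mouse 3 and 686 without iCT mouse 1. For relapse against vehicle, 0 became 971 with array weights, 612 in a fit of these groups alone (24 with both trends removed), 7 with precision weights, 1 with no filter, 1 with the GC trend removed and 3 with length and GC trends removed. Leaving out 1 library gave 0 (without vehicle mouse 1, among others) to 5 (without iCT mouse 1), and 1 without vehicle mouse 4. For relapse against iCT, 1071 became 603 with array weights and 252 in a fit of these groups alone, and 529 (without relapse mouse 2) to 1855 (without iCT mouse 3) when 1 library was left out. It was 1579 without iCT mouse 2 and 593, 583 and 536 without relapse mice 1, 3 and 4. The F test went from 1033 to 583 with no filter, where 16601 genes were tested, and to 439 (without relapse mouse 3) to 2218 (without iCT mouse 2). It was 661, 594 and 544 without vehicle mice 2, 3 and 5, and 570, 474 and 501 without relapse mice 1, 2 and 4. In relapse against vehicle the change of Flt3 was 1.78 in the fits of 3 groups and of these groups alone, with an SE of 0.32 and 0.23. The cause was not tested for the other counts.

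The 3 reversed tests were in relapse against iCT. Without iCT mouse 2 the respiratory chain list went from -0.063 to 0.063 and the ribosomal protein list from -0.031 to 0.122, and after quantile normalization the ribosomal protein list was 0.03. Over the leave-outs these lists ranged from -0.129 to 0.063 and from -0.104 to 0.122. A median changed sign in 20 of the 975, all in relapse against iCT: 12 for the BCL2 family (reported 0.03, lowest -0.333), 3 each for pyrimidine synthesis (reported -0.025, highest 0.085) and ribosomal proteins, and 1 each for purine synthesis (-0.119 to 0.025 without iCT mouse 2) and the respiratory chain. The cause was not tested.

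A block on mouse number gave 197 genes for iCT against vehicle, 372 for relapse against iCT and 216 for the F test. The numbers do not pair the mice: residuals of 10 pairs of mice with the same number correlated by -0.091 to 0.099, and those of 37 other pairs by -0.116 to 0.148.

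Among the calls of lists and named genes, the block on mouse number ended 44, the estimated correlation 38, array weights 29, fry 20, quantile normalization 17 and no filter 15. Leaving out 1 library ended 3 (vehicle mouse 1) to 22 (iCT mouse 2), with 20 each for iCT mouse 1 and relapse mice 3 and 4. A count-based test was not run, because the tables hold no counts. In iCT mouse 1 the median gene at an FPKM of at least 1 rested on 13.9 implied fragments, which limits the precision of low genes there.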

Other observations

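In the list of mast cell, basophil and eosinophil genes 1 of 11 members rose and 3 fell in iCT against vehicle (1 and 4 adjusted over the list alone; camera adjusted p = 0.265). Hdc, the histidine decarboxylase that makes histamine, changed by -1.5 (SE 0.14, adjusted p = 0.00017), the eosinophil granule gene Prg3 by -1.94 (SE 0.27) and the eosinophil lectin gene Siglecf by -1.94 (SE 0.31). From iCT to relapse Hdc changed by 1.27 (SE 0.15, adjusted p = 0.00081). Of 11 genes of MHC class II presentation 0 rose and 4 fell in iCT (the same adjusted over the list alone; camera adjusted p = 0.363), with the peptide loading gene H2-DMa at -0.78 (SE 0.12, adjusted p = 0.00226). H2-DMa had the change of 1.09 from iCT to relapse. Of 41 interferon-stimulated genes 0 rose and 5 fell in iCT (6 fell adjusted over the list alone; camera adjusted p = 0.0709), led by the guanylate-binding gene Gbp3 at -1.67 (adjusted p = 0.00369).

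Growth regulators moved both ways. The list of cyclin-dependent kinase inhibitors and D cyclins had 4 of 14 members higher and 1 lower in iCT (4 and 2 adjusted over the list alone; camera adjusted p = 0.3). Besides Cdkn1a, the cyclin gene Ccnd2 rose by 1.5 (SE 0.25, adjusted p = 0.00446), and it changed by -1.47 from iCT to relapse. The antioxidant list had 5 of 34 higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.499). Within it Hmox1, haem oxygenase, which is also in the macrophage list, rose by 1.79 and G6pdx, which makes NADPH, by 0.85 (SE 0.12, adjusted p = 0.0022), and they changed by -2.12 and -0.78 from iCT to relapse.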
